A study of Homo sapiens with 12 samples.

How the data were processed

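MicroRNAs (miRNAs), small RNAs that repress messenger RNAs, were profiled in 12 samples of T-cell lymphoblastic lymphoma, a cancer of immature T cells, all taken at diagnosis. The labels placed 9 samples in a nodal tumour group, biopsies frozen at surgery, and 3 in a pleural effusion group, mononuclear cells recovered from fluid of the chest cavity after lysis of red cells. Per the labels' protocols, total RNA was extracted with a phenol reagent, labelled with a single dye (Cy3) and hybridised to Agilent human miRNA arrays, with no technical replicates. Replicate numbers were given in accession order and serve only as names, so no sample was paired with another. The labels gave no array batch and did not state that every sample came from a separate patient. The p-values set group differences against the spread between these samples, which may be partly technical. If some samples shared a patient, the p-values may be too small.

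The deposited values were linear intensities, one per miRNA and array, with an error and a detection flag, per the file headers. The intensity was the total gene signal, a summary over the probes of a miRNA, which was background-subtracted and could be negative, per the file headers and the values. Agilent Feature Extraction 9.5.1 was named as the image analysis software, per the submitters' processing notes. No normalization between arrays was recorded in the sources used here, and the deposited medians and upper quartiles differed between arrays. The deposited detection flag was a 0 or 1 per miRNA and array, and its rule was not given in the sources used here. Each file held 821 rows, of which 723 were human miRNAs, 76 were viral miRNAs and 22 were array controls. No depth exists for an array, and the number of arrays limits the precision.

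Intensities under 1 were set to 1, log2 was taken, and the 799 human and viral rows were quantile normalized with limma 3.58.1 in R 4.3.3. Quantile normalization assigns the few most intense miRNAs the same set of values on every array, so that differences among them are coarse. Human miRNAs detected in at least 3 of the 12 samples were tested, which left 310. Groups were compared with limma's moderated test with a variance trend on the mean over all 12 samples, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a single miRNA below comes from this limma fit unless another setting is named. In 20 simulations on the means and spreads of the 310 miRNAs, 60 miRNAs were changed in each. The fit recovered 16.0% of changes of 1 log2 unit, 62.3% of changes of 2 and 95.8% of changes of 4. It called 0.700% of unchanged miRNAs. The simulated values were independent between miRNAs and had the same SD in both groups. In the data, limma's array weights, lower for more variable arrays, were 0.27 to 0.76 for effusions and 0.69 to 2.96 for nodal tumours. The rates for the real data may therefore differ.

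Before the data were examined, 20 lists of miRNAs were fixed for clusters, families and cell types, together with the tests, the alternatives and the rule for named miRNAs. Lists with at least 3 tested members (18 of them) were tested with limma's camera, two-sided, with a preset correlation of 0.01, adjusted over the lists. A score per sample, the mean log2 value of a list's tested members, was compared between groups by an exact permutation test over all 220 splits of the samples, two-sided, adjusted over the 20 lists. Within the 9 nodal tumours, 9 relations between scores were tested with Pearson's r and Spearman's rho and an exact permutation of all pairings, two-sided, adjusted over the 9. The rule named the 10 largest changes in each direction among calls, up to 4 called members per list, 20 fixed miRNAs, the 15 most abundant miRNAs of each group and the 10 most variable ones across nodal tumours among those detected in all 9. Any other miRNA in the text, including further list members, was chosen after its values were seen. miR-199a-3p, one of the 20, was read through the probe for miR-199b-3p, which has the identical mature sequence. Near-identical family members, such as those of the let-7 family or of the miR-17 cluster and its paralogs, can share a probe's signal and their separate values are uncertain.

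Alternatives were the values as deposited on the log2 scale, a 75th percentile scaling, no filter, detection in all samples of a group, a floor of 4, robust moderation, no variance trend, array weights, an added minimum of 2-fold, other list tests and scores, and the omission of each sample in turn. A correction for hairpin GC content was added after seeing the data. Where no array of a group detected a miRNA, a lower bound on the fold was computed by placing that group at the mean of its arrays' highest undetected values. Hairpin genes, host genes and GC content came from the GENCODE v29 annotation of GRCh38, matched by name, since the arrays carry no coordinates; 298 of the 310 tested miRNAs (96.1%) matched. Scores, permutations and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Viral rows entered the normalization and no test between groups.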

Results

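The 12 arrays covered 9 nodal tumours and 3 pleural effusions of T-cell lymphoblastic lymphoma. Between 210 and 302 human miRNAs were detected per array, with a mean of 269 ± 22.8 (SD, n = 9) in nodal tumours and 253 ± 46.2 (SD, n = 3) in effusions. Of the 723 human miRNAs, 164 were detected in all 12 arrays and 331 in none. The total human intensity ran from 51922 to 235598, and the 10 most intense miRNAs held 48.2% to 68.1% of it. Effusion replicate 2 had the lowest total, the fewest detected miRNAs and the highest negative control (28.1). Arrays of any pair differed by a median of at least 0.33 on the log2 scale, so no 2 arrays held the same values.

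The miRNAs of the nodal tumours were ranked by median signal, which also depends on each probe. miR-142-3p, which is restricted to blood cells, had the highest median (13.48 log2, range 13.48 to 14.44 over 9 tumours), followed by miR-21 (12.96), an oncogenic miRNA of many tumours, and miR-16 (12.44). miR-923, which is a fragment of ribosomal RNA and no longer counted as a miRNA, stood at 12.44. The next ranks held let-7a (11.87), miR-19b (11.87) of the miR-17 cluster, miR-15a (11.63), miR-181a (11.63), which is abundant in thymocytes, miR-451 (11.63) of red cells, let-7f (11.42) and miR-20a (11.42). miR-15b (11.27), let-7g (10.85), let-7b (10.73) and miR-106b (10.64) completed the 15. In the effusions miR-923 (14.44), miR-21 (13.48) and miR-142-3p (12.96) led, and 12 of the 15 highest-ranked miRNAs were shared with the nodal tumours. The 3 that entered were miR-223 (10.55), miR-342-3p (10.41) and miR-130a (10.36), in place of miR-451, let-7b and miR-106b.

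The labels separate the samples by the tissue they came from, and the comparison between effusions and nodal tumours asked which miRNAs differed between the lymphoma sampled as solid tissue and as cells in fluid. Of the miRNAs of connective tissue and of blood vessels tested, 10 of 14 and 2 of 4 were lower in the effusions, and for miR-145, miR-143 and miR-126 every effusion lay below every nodal tumour. miR-145 and miR-143, a pair made by smooth muscle cells and fibroblasts, were detected in no effusion and were at least 14.9-fold and 6.09-fold lower when set against the highest undetected signals. Their fitted changes of -6.84 (SE 0.40) and -5.57 (SE 0.41) log2 units, like those of other miRNAs at or near the floor in most samples of a group, depend on the floor. miR-126, the main miRNA of endothelial cells, differed by -6.81 (SE 0.60), from 10.16 ± 0.80 (SD, n = 9) to 3.35 ± 1.54 (SD, n = 3). A set of 6 miRNAs was higher in the effusions, of which miR-135b alone was called in every setting that tested it.

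Of the 310 miRNAs tested, 22 passed the threshold in limma, 16 lower and 6 higher in the effusions. In the same fit 68 had an unadjusted p under 0.05. The lower calls included miR-30a (-1.91, adjusted p = 0.00901), miR-30a* (-2.29, adjusted p = 0.0404) and miR-101 (-1.91, adjusted p = 0.0393), which are on no fixed list. Of these, miR-30a was also called as deposited and with 75th percentile scaling, miR-30a* only as deposited and miR-101 in neither. The groups' values did not overlap for 16 of the 22, and for 20 of all 310, where chance gives 0.909% of miRNAs or 2.82. The median change of all tested miRNAs was -0.04 after quantile normalization, -0.33 with the values as deposited and -0.09 with 75th percentile scaling. Each of the latter settings also made 16 of the 22 calls, but not the same 16. miR-30a* was called only as deposited and miR-365 only with 75th percentile scaling. Without effusion replicate 1 the count rose to 77, with 49 lower and 28 higher, and array weights brought it to 14. Over the miRNAs detected in both arrays, effusion replicate 1 correlated with the nodal tumours at Pearson's r from 0.86 to 0.94. Its r with effusion replicates 2 and 3 was 0.74 and 0.80, and these 2 had 0.78 with each other. Every pair of nodal tumours reached at least 0.89, so the effusions were less alike than the nodal tumours.

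**Figure D1:**
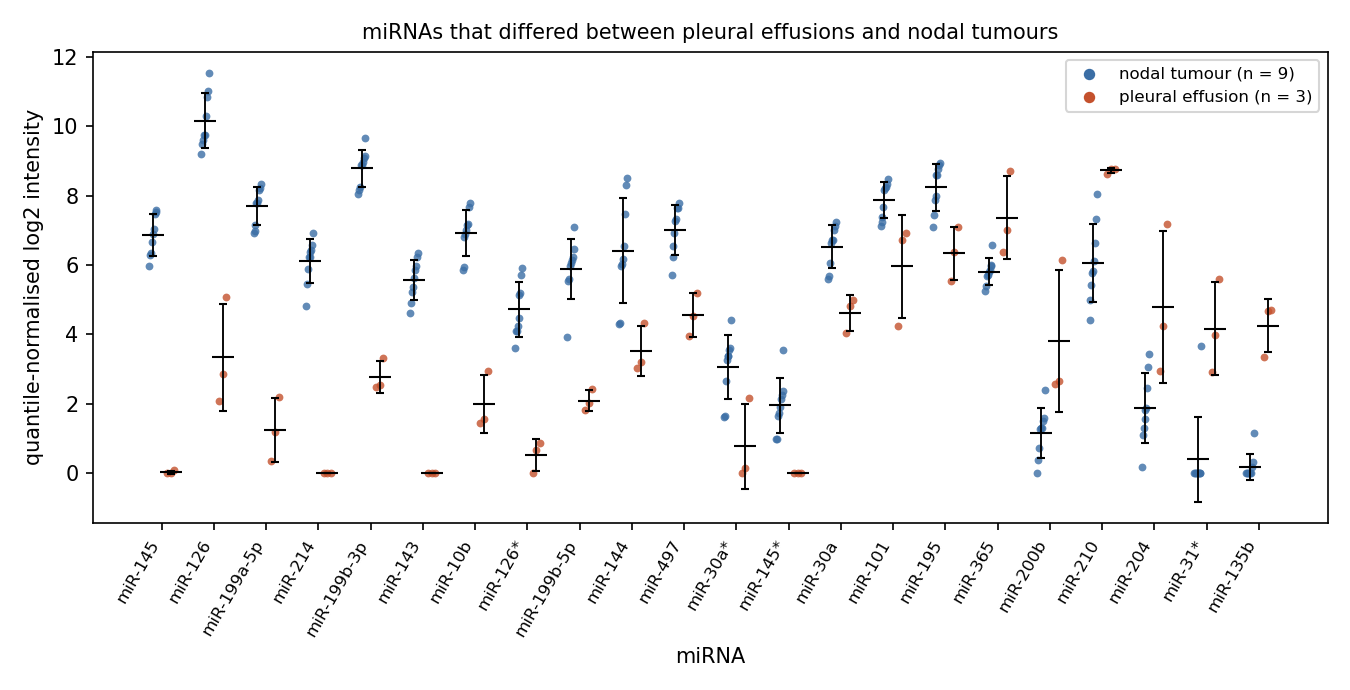
The 22 miRNAs that passed the limma threshold, by change; points are samples (spread sideways by rank), horizontal marks group means and bars the SD, on the quantile-normalised log2 intensity scale. The effusions lay below all nodal tumours for miR-145, miR-126 and miR-214 and above all of them for miR-135b and miR-210.

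The stromal list, miRNAs of fibroblasts and smooth muscle, held 22 entries, of which 21 were on the array and 14 were tested. In the effusions 10 of the 14 were lower, 0 higher and 4 did not pass, and the count adjusted over the list alone was also 10. miR-199a-5p changed by -6.45 (SE 0.44, adjusted p = 3.04e-08), miR-214 by -6.11 (SE 0.42, adjusted p = 3.04e-08) and miR-199b-3p by -6.00 (SE 0.38, adjusted p = 1.77e-08), all transcribed within dynamin genes on the opposite strand. miR-145 (adjusted p = 1.27e-08), miR-143, miR-214, miR-199a-5p and miR-10b were detected in 9 of 9 nodal tumours and 0 of 3 effusions. Set against the highest undetected signals, miR-199a-5p was at least 26.5-fold, miR-10b at least 15.6-fold and miR-214 at least 8.82-fold lower. miR-10b, which lies within HOXD3, changed by -4.93 (SE 0.47, adjusted p = 1.40e-06) and miR-199b-5p by -3.79 (SE 0.51, adjusted p = 7.56e-05). The remaining calls were miR-497 (-2.45), miR-195 (-1.90) and miR-145*, the last detected in 4 nodal tumours only. The call of miR-145* was not made as deposited (adjusted p = 0.101), with 75th percentile scaling (adjusted p = 0.0845) or with the GC trend removed (adjusted p = 0.0658). The members that did not pass were miR-152 (-0.31), miR-125b (0.48), miR-99a (0.63) and miR-100 (1.37), and for the latter 3 effusion replicate 2 held the highest value of all samples.

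Camera placed the stromal list lower in the effusions (adjusted p = 2.49e-11), with a median change of -3.12, or -2.53 with undetected members at their bounds. That call was not made in camera with a correlation estimated from the data, which was 0.48 (adjusted p = 0.252). Limma's fry, another planned list test, which does not compare a list with other miRNAs, called it (adjusted p = 2.94e-05). The stromal score fell by 3.13 log2 units, from 6.25 ± 0.52 (SD, n = 9) to 3.12 ± 0.64 (SD, n = 3), with all 3 effusions below all 9 nodal tumours (exact permutation p = 0.00455, the smallest that 220 splits allow, adjusted p = 0.0455).

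Of the 4 endothelial miRNAs tested, 2 were lower and 2 did not pass, and 3 passed when adjusted over the list alone. miR-126 (adjusted p = 5.20e-07) was detected in 9 nodal tumours and 1 effusion. Its star strand miR-126* changed by -4.21 (SE 0.51, adjusted p = 2.23e-05), was undetected in the effusions and was at least 3.38-fold lower. Both derive from an intron of EGFL7 on chromosome 9 (GRCh38, 136670602 to 136670686). miR-139-5p had a change of -2.05 (adjusted p = 0.139) and miR-139-3p of -1.14 (adjusted p = 0.260). Camera gave the endothelial list as lower (adjusted p = 0.000645), and not with the estimated correlation of 0.71 (adjusted p = 0.386). In fry it was called (adjusted p = 0.000578). The endothelial score fell by 3.55, from 4.96 ± 0.85 (SD, n = 9) to 1.41 ± 0.83 (SD, n = 3), with every effusion under every nodal tumour (exact permutation p = 0.00455, adjusted p = 0.0455).

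The hairpins of the leading stromal miRNAs lie at few loci in the GENCODE v29 annotation of GRCh38. miR-143 (chromosome 5, 149428918 to 149429023) and miR-145 (149430646 to 149430733) sit in an exon and an intron of the long non-coding RNA CARMN. miR-214 (chromosome 1, 172138798 to 172138907) sits in an exon of DNM3OS, the antisense transcript of DNM3, and a hairpin of miR-199a (172144535 to 172144644) in an intron of it. A further miR-199a hairpin lies on chromosome 19, antisense to DNM2, and the miR-199b hairpin on chromosome 9, antisense to DNM1. The probe for miR-199b-3p also reads the identical miR-199a-3p, so its signal cannot be assigned to any of these loci alone.

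Of the 6 miRNAs higher in the effusions, only miR-200b belonged to a fixed list. miR-135b was detected in 3 of 3 effusions and 0 of 9 nodal tumours and changed by 4.06 (SE 0.47, adjusted p = 1.37e-05), at least 2.77-fold. miR-31* changed by 3.76 (SE 0.78, adjusted p = 0.00616) and was detected in 3 effusions and 1 nodal tumour; with a floor of 4 the change was 1.98 (adjusted p = 0.0277). miR-210, the miRNA induced by low oxygen, rose by 2.66 (SE 0.61, adjusted p = 0.0129), from 6.06 ± 1.13 (SD, n = 9) to 8.72 ± 0.08 (SD, n = 3). It was not called with the values as deposited (2.13, adjusted p = 0.215) or with 75th percentile scaling (2.36, adjusted p = 0.0581), and 17 of the 22 alternatives kept its call. miR-204 (2.91, SE 0.80, adjusted p = 0.0402) and miR-365 (1.56, SE 0.44, adjusted p = 0.0404) completed the group together with miR-200b, and these 3 were called in 11, 9 and 10 of the 22 alternatives. Effusion replicate 2 had the highest value of miR-31*, miR-204, miR-200b and miR-365, and leaving it out left 1 of the tested miRNAs, miR-210, higher in the effusions. miR-135b was then no longer tested, since 2 effusions fall short of the detection filter. Without it the changes were 3.11 for miR-31* (adjusted p = 0.0640), 1.73 for miR-204, 1.48 for miR-200b and 0.89 for miR-365 (adjusted p = 0.289 for the latter 3).

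Lists for other cell types a biopsy or fluid could hold showed few calls. Among 4 erythroid miRNAs, miR-144 fell by 2.88 (SE 0.81, adjusted p = 0.0404), a call made in only 6 of the 22 alternatives, while miR-451, from the same transcript, had a change of -1.40 (SE 0.998, adjusted p = 0.394). Red cells had been lysed in the effusions only, per the labels' protocols. Among 3 epithelial miRNAs, miR-200b rose by 2.63 (SE 0.71, adjusted p = 0.0394), miR-200c had a change of 0.59 (adjusted p = 0.665) and miR-141 of -0.56 (adjusted p = 0.698). None of 6 myeloid miRNAs passed, and 1, miR-22 (1.61, adjusted p = 0.0532), passed when adjusted over the list alone. The change of miR-22 was 0.76 (adjusted p = 0.516) as deposited and 0.99 (adjusted p = 0.277) with 75th percentile scaling. miR-223, the leading myeloid miRNA, had a change of 0.76 (SE 0.82, adjusted p = 0.570).

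The lists of the lymphoid cells and of the tumour had 0 calls. For the pan-haematopoietic pair, miR-142-3p had a change of -1.95 (SE 0.64, adjusted p = 0.0923) and 1 of 2 members passed when adjusted over the list alone. The change of miR-142-3p was -2.69 (adjusted p = 0.0164) without effusion replicate 1 and -0.65 (adjusted p = 0.428) without effusion replicate 2. The level of miR-142-3p was 9.43 in effusion replicate 2 and at least 12.96 in the others. Among 8 miRNAs of mature lymphocytes and immune activation, the changes of miR-150 (0.64), miR-155 (0.20), miR-146a (-1.09) and miR-342-3p (-0.22) did not pass, and the list's mean change of 0.12 turned to -0.33 with the values as deposited and to -0.10 with 75th percentile scaling. None of 9 members of the miR-17 cluster, a polycistron amplified in lymphomas, passed, with miR-17 at -0.43 (adjusted p = 0.511), miR-19b at -0.69, miR-20a at -0.62 and miR-92a at 0.12. Its mean change was -0.83 (camera adjusted p = 0.285, or 0.812 with the estimated correlation of 0.76), and without effusion replicate 1 it was -1.53 (camera adjusted p = 0.0109 with the preset correlation of 0.01). miR-181a (0.31), miR-26a (-0.19), miR-21 (0.04) and let-7a (-0.07) did not pass either. let-7b had a change of -1.61 (adjusted p = 0.140), which passed with the values as deposited (-2.25, adjusted p = 0.01), with 75th percentile scaling (-2.01, adjusted p = 0.0229) and without effusion replicate 2 (-2.90, adjusted p = 1.47e-05). Without effusion replicate 1 the change was -0.80 (adjusted p = 0.327).

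The score differences of the remaining lists did not pass the exact permutation test (adjusted p from 0.394 to 0.959). They were -0.31 for the miR-106b cluster, -0.63 for the miR-106a cluster, -0.12 for the oncogenic miRNAs of T-cell leukaemia, -0.38 for the miR-181 family and -1.72 for the pan-haematopoietic pair. For the myeloid list the difference was 0.48, for the erythroid list -1.42, for the imprinted cluster of chromosome 14 0.28 and for the epithelial list 0.89. The let-7 family differed by -0.28, and with 75th percentile scaling by -0.60, which passed (exact permutation, adjusted p = 0.0303). The difference was -0.57 for the miR-29 family, with 1 member lower when adjusted over the list alone, and -0.23 for the miR-34 family. The cluster of miR-221 and miR-222 differed by -0.56. The score of the miR-23, miR-24 and miR-27 clusters differed by 0.62, and by -0.03 with the values as deposited. Without effusion replicate 1 the mean change of this list was 1.13, and it passed in camera with the preset correlation (adjusted p = 0.0395). Over all samples its camera adjusted p was 0.428 with the preset correlation and 0.812 with the estimated correlation of 0.42. Muscle miRNAs had a mean change of -0.03 with a median of 0.30, and the miR-15 and miR-16 family a mean of -0.15 with a median of 0.05, so that mean and median differed in sign.

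**Figure D2:**
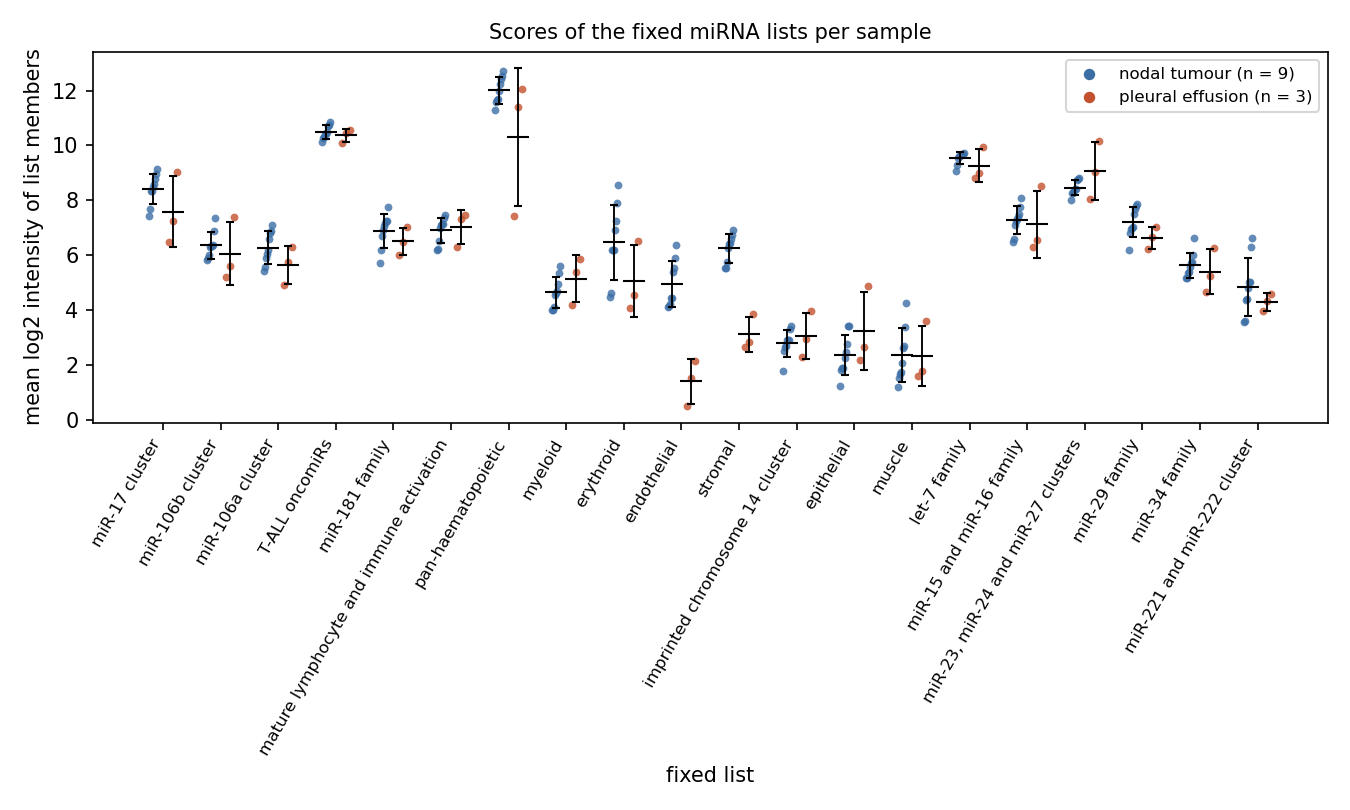
Scores of the 20 fixed lists, the mean quantile-normalised log2 intensity of the tested members, for each nodal tumour (n = 9) and effusion (n = 3); points are spread sideways by rank, horizontal marks are means and bars the SD. The stromal and endothelial scores of the effusions, at most 3.86 and 2.17, lay below those of all nodal tumours, at least 5.52 and 4.13.

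Within the 9 nodal tumours, relations between the scores addressed how far the tumours differed in admixed cells. None of the 9 passed after adjustment. The stromal and endothelial scores had the highest correlation (Pearson's r = 0.78, exact permutation p = 0.0190, adjusted p = 0.171; Spearman's rho = 0.65, exact p = 0.0666, adjusted p = 0.486), which was 0.71 without the 2 tumours farthest from the median stromal score. With 75th percentile scaling it was 0.80 and passed (adjusted p = 0.0320, exact permutation). The stromal score against the miR-181 family gave r = -0.59 (exact permutation p = 0.0966, adjusted p = 0.420) and rho = -0.42 (exact p = 0.270, adjusted p = 0.578), and r = -0.29 without 2 tumours. miR-223 against the miR-17 cluster gave r = -0.54 (exact permutation p = 0.140, adjusted p = 0.420) and rho = -0.33 (exact p = 0.385, adjusted p = 0.578), and r = -0.18 without 2 tumours. The stromal score against the other 6 lists gave r from -0.33 for the miR-17 cluster to 0.28 for the myeloid list (exact permutation p from 0.388 to 0.616, adjusted p = 0.616) and rho from -0.58 to 0.35 (exact p from 0.108 to 1, adjusted p from 0.486 to 1). Without 2 tumours these r ran from -0.50 to 0.19.

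The nodal tumours differed among themselves in a limited set of miRNAs. Of 193 miRNAs detected in all 9, 23 had an SD above 1 log2 unit, and the median SD was 0.58. miR-10a, which lies in the HOXB locus, varied most, with an SD of 1.87 and a range of 3.70 to 10.09. The red cell miRNAs miR-451 (SD 1.60) and miR-144 (SD 1.51) followed, then miR-135a* (SD 1.48) and miR-801 (SD 1.47), a fragment of a small nuclear RNA. miR-223 (SD 1.47) ranged from 7.68 to 11.87, an 18.3-fold span. miR-150 (SD 1.35), which rises as lymphocytes mature, ranged from 6.28 to 10.73, and miR-146a (SD 1.27), an immune response miRNA, from 4.63 to 9.14. miR-923 (SD 1.33) and miR-106a* (SD 1.22) were the other two. These variable miRNAs did not include any of the called stromal or endothelial ones. With the values as deposited, 41 miRNAs exceeded the SD of 1.

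**Figure D3:**
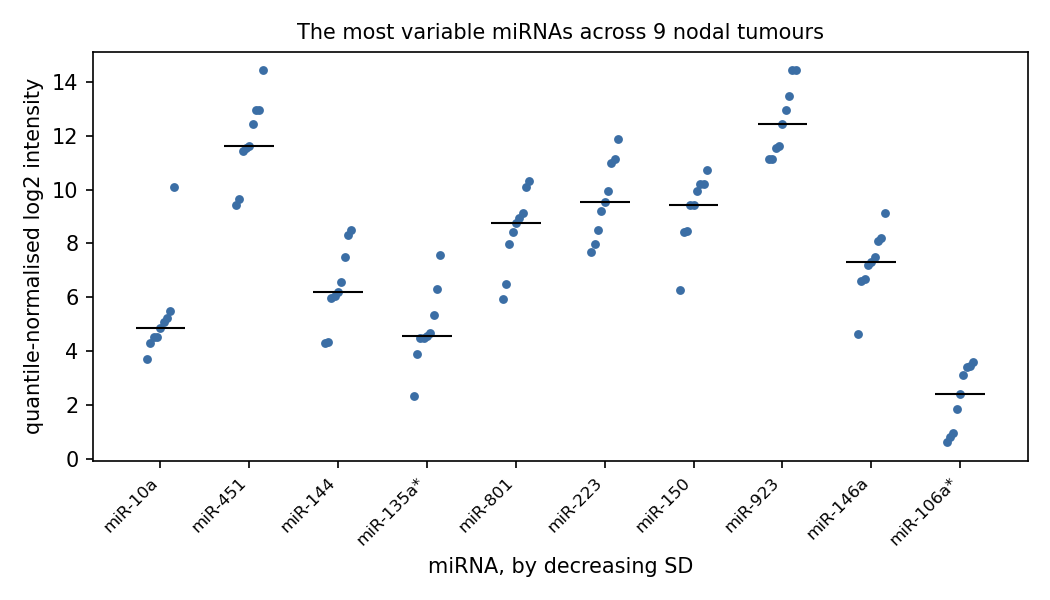
The 10 miRNAs with the largest SD across the 9 nodal tumours, one point per tumour (spread sideways by rank) with the median as a line, on the quantile-normalised log2 intensity scale. miR-10a reached 10.09 in a single tumour, while the others lay between 3.70 and 5.49.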

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

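Of the 73 values screened across the 9 nodal tumours, 6 had a single tumour far from the rest. The cutoff's nominal rate of about 1 in 20 does not apply to this set. The screen included miRNAs named for their large spread across these same tumours, such as miR-10a. miR-10a was 10.09 in nodal replicate 2 and at most 5.49 elsewhere. miR-31* was 3.66 in nodal replicate 6 and at the floor in the others. miR-135b was 1.15 in nodal replicate 7, with the next tumour at 0.33, but it was detected in no nodal tumour and the highest undetected value of that array was 2.87, so this difference lies within background. miR-199b-5p was lowest in nodal replicate 5 (3.94, next 5.55), miR-106b in nodal replicate 7 (10.01, next 10.48) and miR-342-3p in nodal replicate 4 (9.04, next 10.09).

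In the weighing that follows, the tests of overall signal, of the leukocyte miRNAs and of viral infection were chosen after the results were seen, and so was the setting that removes the GC trend. The first pattern is the low level of 12 called stromal and endothelial miRNAs in the effusions, with a median change of -5.25, or -3.47 with undetected members at their bounds. The tables argue against lower overall signal, since all tested miRNAs as deposited shifted by a median of -0.33 while these 12 shifted by -5.40, and against a trend with hairpin GC content, since 11 of the 12 were still called with each array's trend removed. Stroma and vessels present in the biopsies and scarce in the fluid are a candidate source: across the nodal tumours alone the 12 varied together, with a median pairwise r of 0.70 against 0.00076 for random sets, at percentile 100 of 10000 sets matched on expression. For the 59 pairs whose hairpins, matched by name, lie at different loci the median was 0.69. Some of these pairs can still share a transcript or signal, since the miR-199b-3p probe also reads the identical miR-199a-3p. Transcription from a shared locus is therefore not fully removed. However, 4 of the 14 stromal members tested did not pass, 3 of them with higher means in the effusions, and miR-195 and miR-497 were detected in all 3 effusions. The higher means rest on effusion replicate 2: in effusion replicates 1 and 3, miR-125b was 7.12 and 7.28, below the nodal minimum of 7.58, and miR-100 (6.23 and 5.93) and miR-99a (4.72 and 5.91) lay within the nodal range. Since collection differs with the group, the handling of biopsies against cells from fluid stays open.

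The second pattern is effusion replicate 2, where miR-142-3p was 4.48 log2 units under the nodal mean (deposited intensity 232, lowest other sample 8270) and miR-142-5p was 5.42 against at least 9.09 elsewhere. The leukocyte miRNAs miR-150, miR-155, miR-223, miR-342-3p and miR-146a had a median difference of 0.43 there, and none shows a like fall. They were chosen after the values were seen, so they bear on the share of blood cells only as far as they mark such cells. The miR-17 cluster score (6.50) was the lowest of all samples. Of the stromal list, miR-125b and miR-100 were highest there, although that list's score (3.86) lay below all nodal tumours. A lower share of blood cells therefore stays open. Removing the array's trend on hairpin GC left the difference of miR-142-3p at -3.97. This sample had 27 miRNAs more than 1 log2 unit below and 24 more than 1 above all other samples. In effusion replicate 3 the like counts were 2 below and 22 above, so only the count below sets effusion replicate 2 apart. Effusion replicate 2 also had the lowest total signal (51922), the fewest detected miRNAs (210) and the highest negative control (28.1), so sample quality stays open. The design gives no group for it, so no biological explanation other than the share of blood cells was tested.

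The third pattern is the signal of viral probes, which no comparison used: 6 of the 76 viral miRNAs were called detected in all 12 arrays and 54 in none. Infection of every sample with Epstein-Barr virus, cytomegalovirus or Kaposi's sarcoma herpesvirus (KSHV) is argued against, since at most 12.5% of the miRNAs of any of these was detected in all arrays, although most KSHV miRNAs come from a shared cluster. For herpes simplex virus 1 the share was 50% of only 2 probes, too few to decide. For the 6 as a set, a constant signal of the array is argued against by their SD across nodal tumours, at a median percentile of 78.4 among human miRNAs of like intensity. The probe for ebv-miR-BART13 lay at percentile 1.92, so for it a constant signal stays open, while the others lay at 52.6 to 83.7. Binding of human RNA to these probes was not tested and stays open.

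For the count of called miRNAs, 2 of 100 splits of the samples, drawn from 220 and with the real one included, gave 22 or more. So high a count was rare among these splits, but the real split did not give the highest. The highest other split, which held 2 of the 3 effusions, gave 23. For the count of called lists in camera, chance cannot be excluded, because 69 of 100 splits gave 2 or more and the highest other gave 8.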

How the results depend on the processing

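The GC trend setting was chosen after seeing the data, the other alternatives before. Of the 16 called miRNAs that the naming rule covers, 10 stayed called in every setting that tested them: miR-145, miR-126, miR-199a-5p, miR-214, miR-199b-3p, miR-143, miR-10b, miR-126*, miR-199b-5p and miR-135b. miR-144 lost its call in 16 settings, miR-365 in 13, miR-200b in 12, miR-204 in 11, miR-210 in 5 and miR-31* in 2; the causes were not tested. Signal over background limits what was tested: 331 human miRNAs were detected in no array and did not enter the comparison of the 310.

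The count of 22 was 14 with array weights and 15 to 77 when a sample was left out, the 77 without effusion replicate 1; the cause was not tested. Without effusion replicate 2 the count was 18, with 1 higher and 17 lower; miR-135b was not tested there or without another effusion, since the filter asks for 3 arrays that detect it. miR-142-3p, miR-15a (-1.37), miR-106b (-1.39) and the lists of the miR-17 cluster and of the miR-23, miR-24 and miR-27 clusters passed only without effusion replicate 1 among the omissions, let-7b only without effusion replicate 2 and miR-801 (-2.28) only without nodal replicate 7. The camera count of 2 lists was 4 with no filter, 0 with an estimated correlation and 2 to 4 when a sample was left out, the 4 without effusion replicate 1. The lists gained with no filter were the miR-17 cluster (-0.64, camera adjusted p = 0.0353) and the imprinted cluster of chromosome 14 (0.38, camera adjusted p = 0.0104). The 2 score differences became 0 whichever sample was left out, since 165 or 55 splits allow no p below 0.00606 or 0.0182. Of the score correlations 1 passed with 75th percentile scaling, against 0, and 41 miRNAs had an SD above 1 as deposited, against 23; the cause was not tested.

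Reversed signs were confined to results that did not pass. As deposited, they were miR-92a (-0.41), miR-181a (-0.20), miR-150 (-0.18), miR-155 (-0.31), miR-21 (-0.0027), let-7f (-0.64), miR-15b (-0.10), the mature lymphocyte list (-0.33) and the miR-23, miR-24 and miR-27 clusters (-0.028). With 75th percentile scaling, they were miR-92a (-0.17), miR-155 (-0.074), let-7f (-0.40), the mature lymphocyte list (-0.10) and muscle (0.0083). Array weights reversed miR-92a (-0.35) and miR-130a (0.26). The GC trend setting reversed let-7a (0.28), miR-16 (0.15), miR-342-3p (0.0081), miR-130a (0.14) and miR-10a (0.30). As medians, the scores of the oncogenic T-cell leukaemia miRNAs (0.084), muscle (0.32) and the miR-15 and miR-16 family (0.0067) reversed, and relative to the array mean they were 0.039, 0.13 and 0.012. Without the 2 farthest tumours, r of the stromal score reversed for the miR-17 cluster (0.19), the pan-haematopoietic pair (-0.26), the myeloid (-0.039), erythroid (0.19) and chromosome 14 lists (-0.50). As deposited, r reversed for the stromal score with the miR-17 cluster (0.0096), the miR-181 family (0.20) and the erythroid list (0.22), and for miR-223 (0.10).

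Leaving out a sample gave ranges that crossed 0: miR-21 -0.58 to 0.81, miR-92a -0.19 to 0.64, miR-130a -0.25 to 0.28, miR-10a -0.97 to 0.48, miR-155 -0.023 to 0.40, let-7a -0.44 to 0.16, miR-146a -2.0 to 0.088, miR-200c -0.66 to 1.30, miR-26a -0.42 to 0.034, miR-150 -0.072 to 1.36 and miR-342-3p -0.55 to 0.31. For lists they were muscle -0.65 to 0.32, miR-106b cluster -0.97 to 0.12, oncogenic T-cell leukaemia miRNAs -0.21 to 0.015, mature lymphocytes -0.093 to 0.49, chromosome 14 -0.17 to 0.67, miR-15 and miR-16 -0.85 to 0.27 and miR-34 -0.68 to 0.13.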

Other observations

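Effusion replicate 2 held several miRNAs at levels above all other samples. miR-125b was 11.53 there and at most 8.71 in nodal tumours, miR-100 was 9.80 against at most 6.73, and miR-23b lay 3.81 above the nodal mean of 7.19. From the chromosome 19 cluster, let-7e was 10.09, miR-125a-5p 7.48 and miR-99b 7.01, against at most 7.87, 5.46 and 5.34 in nodal tumours, while miR-125a-3p, from the hairpin of miR-125a-5p, was 4.36 there, its lowest value in any sample. miR-224 reached 6.49, where nodal tumours reached at most 3.01. In effusion replicate 3 another set stood out, miR-1225-5p (12.44), miR-940 (10.48) and miR-1228 (8.58), against at most 11.42, 8.51 and 5.85 in nodal tumours. Their hairpins have a GC content of 74.4% to 76.6%, and this array had the steepest trend with GC; with each array's trend removed they were 11.64, 9.59 and 7.74, against at most 11.19, 8.27 and 5.83. These miRNAs, and the removal of the trend, were chosen after the values were seen.

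miR-196b, whose hairpin lies in the HOXA9 gene on chromosome 7, was 8.30 in nodal replicate 8 and 8.09 in effusion replicate 3, and at most 4.11 in the other samples. miR-10a of the HOXB locus was 10.09 in nodal replicate 2 and 6.85 in effusion replicate 2.

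The tests below were fixed before their results were seen. miRNAs encoded within 10 kb of each other were predicted to vary together across the nodal tumours. Over 106 pairs from different hairpins among 184 miRNAs, the median Pearson r was 0.75, above all 10000 relabellings, whose median was 0.02. A large part of these pairs came from the miR-17 cluster and its paralog, the miR-106a cluster, so the median leans on these loci. miRNAs are not independent replicates, and near-identical family members may share signal. The r exceeded 0.5 for 83 pairs and lay below 0 for 7. miR-497 and miR-195 reached 0.96, while let-7e and miR-125a-3p had -0.81 and miR-188-5p and miR-660 -0.71, although each pair shares a cluster.

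The wide range of miR-223 in nodal tumours might come from a varying amount of myeloid cells, a hypothesis. miR-223 and its star strand gave r = 0.87 over 9 tumours (exact permutation p = 0.00349, adjusted over 2 relations 0.00698; rho = 0.90, exact p = 0.00241, adjusted 0.00483), and 0.95 without the 2 farthest. Against the mean of the other 4 myeloid list members r was 0.34 (exact permutation p = 0.376, adjusted 0.376; rho = 0.22, exact p = 0.581, adjusted 0.581), and 0.68 without the 2 farthest. miR-223 and its star strand come from the same hairpin, so their correlation does not bear on which cells vary. The r of 0.34 with the other members lies between the bounds set in advance, so the hypothesis was not decided. Those members were miR-22, miR-22*, miR-132 and miR-212. Whether they mark myeloid cells in these samples was not tested, so this relation may not be able to decide it.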
